A study of Mus musculus with 78 samples.

How the data were processed

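Gene expression was measured in mouse flank tissue on 78 Affymetrix Mouse Genome 430 2.0 arrays, 1 per sample. Per the submitters' processing notes, the authors made the deposited values with MAS5 in GCOS 1.3. The deposited unit is MAS5 signal intensity per probe set on a linear scale. The values bear this out, since none is negative, they run from 0.15 to 186384.77, and the mean of the middle 96% of probe sets is 1500 on every array. Array medians ran from 454.85 to 582.58. No 2 arrays were copies: the highest correlation between any 2 was 0.972, and at most 9 of 45101 values were identical. Arrays give no counting depth; their number limits the precision.

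The platform's annotation gave 1 gene symbol for 34958 of the 45101 probe sets, several for 932, and did not list a gene for 9211, which are unnamed here. Probe sets with several symbols were not named. Of the single-symbol probe sets, 34754 matched the RefSeq gene table by Entrez ID, and 0 symbols needed an update. Per-group analysis used log2(signal + 16). A probe set was kept when its signal exceeded 331, the 40th percentile of all values, on at least 6 arrays, and 26696 single-symbol probe sets passed. Each gene was represented by its brightest probe set, which left 14718 genes.

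Groups came from the labels: control day 0, and untreated, G6 and DC101 at days 5, 20 and 60. Each held 8 arrays, except DC101 day 60 with 6. The design text speaks of at least 5 animals per group, and the labels do not tie arrays to animals, so some arrays may share an animal and the p-values may then be too small. The running numbers in the sample titles are not shared between groups and gave no pairing across groups. 1 limma (3.58.1, R 4.3.3) linear model was fitted over all 10 groups with eBayes and an intensity trend. It gave 14 comparisons and 4 interaction contrasts, all two-sided, with Benjamini-Hochberg adjustment over the 14718 genes and a threshold of 0.05. Fold changes are on the log2 scale with the model's standard error (SE). Where every array of the dimmer group lay below the filter level, the fold is also given as a lower bound, the brighter group's mean over that level.

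There were 31 gene lists fixed before the data were examined, with 626 of 676 entries matched by symbol or synonym. Of the matches 2 went by synonym to another gene, Loxl2 to Loxl3 (wound matrix) and Gpi1 to Pigq (hypoxia and glycolysis). They were kept, and lists without them, tested after the results were seen, changed the count of lists passing in 1 of 18 comparisons (17 to 16, the DC101 effect at day 60 against day 20). They were tested against all other genes with camera (limma) at a preset correlation of 0.01 for lists with at least 5 members, and again with an estimated correlation. Members past the threshold were counted over all genes tested and, separately, adjusted over the list alone. An Ad-VEGF score per array was the mean of genes higher minus the mean of genes lower, by at least 2-fold and past the threshold, in untreated against control tissue at the other 2 days. Score differences were compared by exact two-sided permutation of arrays, with adjustment over 9 comparisons. Overlaps between comparisons that share a group were set beside the product of list sizes over genes tested and values with the shared group's arrays split between the comparisons. The split took every other array, so arrays of adjacent running numbers fell in different parts. Covariances were also set beside those of simulated unchanged groups, whose genes were drawn independently of each other. Shared calls were not, since the adjusted threshold leaves such groups without calls.

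Named genes followed a rule fixed at the same time as the lists. In the 9 main comparisons (untreated against control, each antibody against untreated) these are the 8 largest rises and 8 largest falls past the threshold, passing over clone and predicted genes, and the 2 largest changes past the threshold in each list that passed. In the other comparisons they are the 4 largest in each direction. Vegfa, Flt1 and Kdr are always given, and 14 genes have their level in every group reported. The text gives the members of this set that carry each comparison. Genes of 4 marker sets (mammary gland, clock output, clock opposite phase, glucocorticoid response) were written down after the data were seen.

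The model and list test were tested on simulated data for untreated day 5 against control with 14718 genes. There, 35% of 100 genes changed by 0.5 log2 and 76% of 100 changed by 1 were recovered, with 2 unchanged genes among 114 calls. The unchanged comparison gave 0 called genes and 0 called lists, and a list shifted in the simulation had an adjusted p of 2.07e-10. Alternatives fixed at that time were pseudocounts of 1 and 64, no filter, quantile normalization, the mean of a gene's probe sets, array weights, only the groups compared in the fit, a 2-fold minimum, camera with an estimated correlation, and every other probe set of a named gene. Added after seeing the data were the 3' to 5' signal ratios of the Actb and Gapdh control probe sets as covariates, arrays of adjacent running numbers as a random block (duplicateCorrelation) or averaged, a pseudocount of 256, a fit to 75 arrays without the 3 that correlated least with their group, and fits without arrays of 1 group that stood apart in list levels (51 and 52, 86 and 87, 79, or 13 and 14). Figures were drawn with matplotlib 3.10.9.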

Results

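Flank tissue was profiled in a mouse model in which an adenovirus carrying VEGF-A164 (Ad-VEGF) is injected into the skin and drives the growth of surrogate tumour vessels. Mice were left untreated or received an antibody: DC101, a rat antibody to mouse VEGFR2, at 20 mg per kg, or G6, at 10 mg per kg. The treatment text counts both among antibodies to VEGF receptors and names no target for G6 on its own. There were 8 control arrays at day 0 and 8 arrays each of untreated, G6 and DC101 tissue at days 5, 20 and 60, except 6 for DC101 at day 60. No group received an empty vector, so untreated against control compares virus-injected flank with flank labelled control. The labels do not say that the control flank was left uninjected. The labels do not say whether the day counts treatment or harvest. Levels are log2(signal + 16) with SD.

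Vegfa was examined first. By the brighter of its probe sets it stood at 10.12 ± 0.51 (SD, n = 8) in control tissue, 14.11 ± 0.43 (n = 8) in untreated tissue at day 5, 12.79 ± 1.32 (n = 8) at day 20 and 10.10 ± 0.26 (n = 8) at day 60. It rose by 3.99 (SE 0.39, adjusted p = 9.5e-14) at day 5 and by 2.66 (SE 0.39, adjusted p = 7.1e-08) at day 20, above the control mean in 8 of 8 arrays each time. At day 60 it differed from control by -0.03 (SE 0.39, adjusted p = 0.97). Vegfa with G6 was 13.70 ± 0.53, 12.26 ± 0.90 and 10.16 ± 0.88 at the 3 days (n = 8 each), and with DC101 13.73 ± 0.79 (n = 8), 12.18 ± 1.11 (n = 8) and 10.50 ± 0.35 (n = 6). None of the 6 antibody groups differed from untreated tissue in this probe set (adjusted p from 0.36 to 0.94). Whether either probe set reads the injected or the endogenous transcript was not tested. The other Vegfa probe set went the other way: 11.81 ± 0.36 (n = 8) in control tissue and 9.77 ± 0.19 (n = 8) in untreated tissue at day 5, a change of -2.03 in log2 (adjusted p = 2.2e-15). In that probe set untreated tissue at day 60 also differed from control, by -1.20 (adjusted p = 3.5e-07), and 3 antibody groups stood above untreated tissue of their day: G6 by 1.16 at day 5 (adjusted p = 4.9e-07) and 0.59 at day 20 (adjusted p = 0.032), and DC101 by 0.96 at day 60 (adjusted p = 0.00058).

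**Figure D1:**
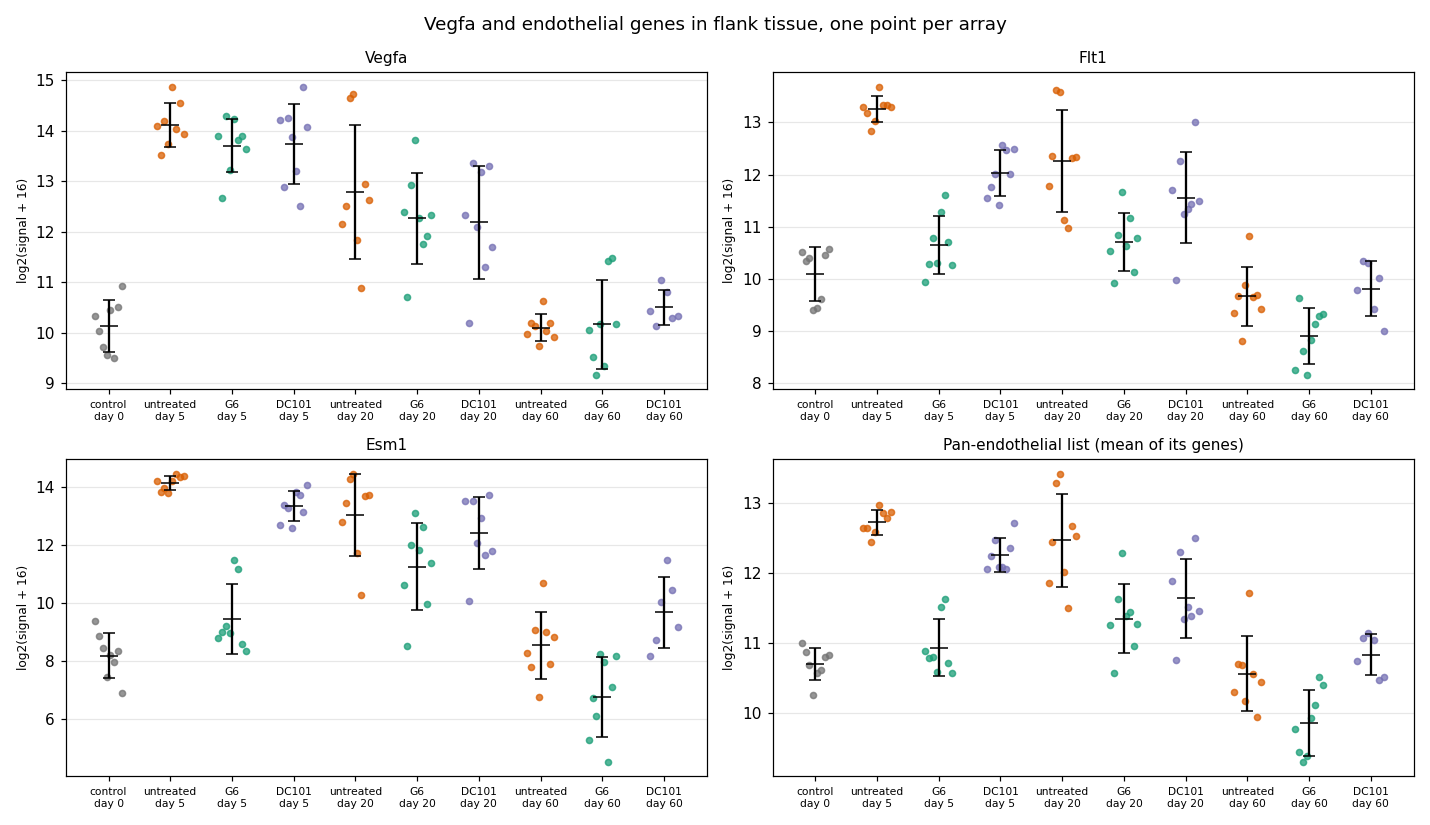
Levels of Vegfa, Flt1, Esm1 and the mean of the pan-endothelial list, as log2(signal + 16), by group; points are arrays and bars are the mean with SD. Vegfa has a mean of 14.11 in untreated tissue and 13.70 with G6 at day 5, while Esm1 has means of 14.15 and 9.44.

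Untreated against control tissue asks how virus-injected flank differed from flank labelled control, whatever the cause. At day 5 the VEGF receptor genes rose with Vegfa: Flt1 (VEGFR1) by 3.15 (SE 0.30, adjusted p = 5.2e-14) and Kdr (VEGFR2) by 2.49 (SE 0.26, adjusted p = 1.6e-12), both in 8 of 8 arrays. Of 28 measured pan-endothelial genes 26 rose and 2 fell, with the same numbers adjusted over the list alone. The largest rises were in Cd93 (3.91, SE 0.31) and Tie1 (3.60, SE 0.38). Of 24 tip-cell and VEGF-induced genes 19 rose and 1 fell, again as adjusted over the list alone. They included Esm1, an endothelial proteoglycan (5.97, SE 0.56, adjusted p = 2e-14), and the potassium channel subunit Kcne3 (6.13, SE 0.41, adjusted p = 2.8e-20), which was at least 31.4-fold higher because every control array lay below the filter level. Arterial and Notch genes followed, with 16 of 19 risen (16 adjusted over the list alone), among them Notch4 (4.01, SE 0.37). Beyond the lists, Fam167b was at least 9.35-fold, Tmem255a at least 16.4-fold and Sox11 at least 7.91-fold higher.

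Stroma, leukocyte and proliferation genes rose beside the endothelium at day 5. In the wound matrix list 19 of 23 genes rose (20 adjusted over the list alone; 18 of 22 and 19 without Loxl3, a mismatched member), with Tnc up by 3.75 (SE 0.30) and Timp1 by 3.54 (SE 0.29). Basement membrane genes rose in 12 of 16 (13), as Nid2 (3.49, SE 0.27), and proteases in 15 of 20 (15), where Mmp13 was at least 6.57-fold higher. Macrophage genes rose in 21 of 26 (21), with Mpeg1 up by 3.38 (SE 0.24), and cell cycle genes in 29 of 30 (29), with Bub1 up by 2.42 (SE 0.41). Neutrophil and acute inflammation genes rose in 18 of 24 (18); the monocyte chemokine Ccl2 rose by 3.84 (SE 0.35). In these counts the number in brackets is adjusted over the list alone.

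The falls at day 5 were in tissue components. All 27 respiratory chain genes fell (27 adjusted over the list alone), Cox7a1 most (-3.44, SE 0.49). Skeletal muscle genes fell in 23 of 24 (23 adjusted over the list alone), as Ampd1 (-3.74, SE 0.62), and adipocyte genes in 13 of 18 (15), as Slc2a4 (-3.21, SE 0.36). The largest falls were in milk protein genes, Csn1s2a (at least 25.4-fold), Csn1s1 (at least 38.3-fold) and Csn2 (at least 26.1-fold), and in the fat synthesis gene Thrsp (-5.20, SE 0.59). Csn2 varied from 8.70 to 16.25 among the control arrays. Limma called 7767 of 14718 genes, 4105 higher and 3662 lower, and 2558 of these changed at least 2-fold. The Gapdh 3' to 5' ratios of these groups did not overlap (0.907 to 1.10 untreated, 0.772 to 0.859 in control), and with the Actb and Gapdh ratios as covariates 6584 genes passed, 6221 of them among the 7767. Of the 31 lists 18 passed with camera's preset correlation, at adjusted p from 4.4e-17 to 0.037, and none with an estimated correlation (adjusted p = 0.17 for pan-endothelial, 0.15 for tip-cell, 0.17 for arterial, 0.17 for respiration, 0.37 for muscle, 0.23 for cell cycle, 0.18 for macrophage, 0.15 for wound matrix, 0.18 for basement membrane, 0.17 for protease, 0.29 for neutrophil and 0.17 for adipocyte genes, each with an estimated correlation).

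At day 20 endothelial genes were again higher than in control tissue. Pan-endothelial genes rose in 25 of 28 (25 adjusted over the list alone), tip-cell genes in 19 of 24 (20) and arterial genes in 16 of 19 (19). Esm1 rose by 4.87 (SE 0.56), Flt1 by 2.17 (SE 0.30, adjusted p = 2.5e-08), Kdr by 1.64 (SE 0.26, adjusted p = 6e-07) and Cd93 by 2.91 (SE 0.31). Venous and lymphatic genes rose in 9 of 16 (10), with the lymphatic genes Mmrn1 up by 3.39 (SE 0.49) and Prox1 at least 1.58-fold. Pericyte and smooth muscle genes rose in 14 of 22 (14), after 11 of 22 (11) at day 5, when the list did not pass (adjusted p = 0.20), as Ndufa4l2 (2.55, SE 0.41) and Higd1b (2.21, SE 0.29). Bracketed counts are adjusted over the list alone.

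Fibroblast matrix genes rose in 12 of 21 at day 20 (12 adjusted over the list alone), with Col12a1 up by 2.33 (SE 0.31), and macrophage genes in 14 of 26 (17), with Mpeg1 up by 1.81 (SE 0.24). Cell cycle genes rose in only 5 of 30 (2). All 27 respiratory genes fell again, and adipocyte genes fell in 13 of 18 (13), as Adipoq (-3.07, SE 0.46). Milk and luminal keratin genes were again the largest falls, with Csn1s2a at least 25.4-fold lower and Krt18 lower too (-4.33, SE 0.54). In total 6056 genes changed, 3342 higher and 2714 lower, 1545 of them at least 2-fold; 5948 passed with the RNA ratios as covariates. Of 31 lists 20 passed and none did with an estimated correlation (adjusted p = 0.097 for pan-endothelial, 0.09 for tip-cell and 0.09 for arterial, 0.097 for venous, 0.37 for pericyte, 0.52 for fibroblast matrix, 0.54 for macrophage, 0.71 for cell cycle, 0.097 for respiration and 0.097 for adipocyte genes, each with an estimated correlation).

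At day 60 the endothelial lists did not pass against control and epidermal genes rose. Flt1 differed by -0.43 (SE 0.30, adjusted p = 0.26) and Kdr by -0.44 (SE 0.26, adjusted p = 0.19). Activated keratinocyte genes rose in 12 of 20 (13 adjusted over the list alone), with the antimicrobial peptide Defb3 at least 2.95-fold and Stfa3 up by 3.41 (SE 0.88), and basal and suprabasal genes in 12 of 23 (16), with Krtdap up by 2.14 (SE 0.45). Macrophage genes rose in 15 of 26 (15), as Fcgr3 (1.40, SE 0.26), and cell cycle genes in 14 of 30 (19). Respiratory genes fell in 25 of 27 (27), muscle genes in 14 of 24 (17), adipocyte genes in 11 of 18 (12) and pericyte genes in 8 of 22 (8; list adjusted p = 0.15 without array 79). Untreated array 77 stood apart on the other side in pericyte level (13.2, against 9.93 in array 79 and a control mean of 11.86). No fit left array 77 out. Csn1s2a stayed at least 25.4-fold lower than in control tissue. The 5241 genes called (2758 higher, 2483 lower, 1113 at least 2-fold) became 2360 with the RNA 3' to 5' ratios as covariates; the median Actb ratio was 1.88 in untreated day 60 and 1.31 in control arrays. Of 31 lists 14 passed and none with an estimated correlation (adjusted p = 0.58 for respiration, macrophage, epidermal, keratinocyte, adipocyte and muscle genes, 0.64 for cell cycle genes and 0.68 for pericyte genes, each with an estimated correlation).

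Untreated tissue was also compared between days. From day 5 to day 20 cell cycle genes fell in 26 of 30 (27 adjusted over the list alone) and macrophage genes in 16 of 26 (19), with Trem2 among the largest falls (-3.68, SE 0.42, adjusted p = 7.5e-10), while venous and lymphatic genes rose in 10 of 16 (11). Tip-cell genes fell in 9 of 24 (10). Their adjusted p was 0.31, 0.32, 0.083 and 0.55 with an estimated correlation. Vegfa (-1.32, SE 0.39, adjusted p = 0.0093), Flt1 (-0.99, SE 0.30, adjusted p = 0.013) and Kdr (-0.85, SE 0.26, adjusted p = 0.015) fell, each in 6 of 8 arrays. Untreated day 20 arrays 51 and 52 stood apart from the other 6 (Vegfa 14.64 and 14.72), and without them Kdr fell by 1.31 (SE 0.25) and Vegfa by 1.96 (SE 0.37). The chemokine Cxcl13 rose by 3.27 (SE 0.52). Of the genes tested 2973 changed, 1533 higher and 1440 lower. The count was 1937 with adjacent arrays averaged, 5233 with array weights and 2375 with the RNA ratios as covariates.

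From day 20 to day 60 pan-endothelial genes fell in 25 of 28 (25 adjusted over the list alone), tip-cell genes in 20 of 24 (21), pericyte genes in 17 of 22 (19) and basement membrane genes in 14 of 16 (14). These lists also passed with an estimated correlation, at adjusted p = 0.019, 0.0042, 0.043 and 0.035, as did arterial genes (0.019) and the VEGF and angiopoietin family (0.043). The falls included Esm1 (-4.52, SE 0.56), Fam167b (-4.43, SE 0.50), Ushbp1 (-3.91, SE 0.41), Kcne3 (-3.63, SE 0.41), Flt1 (-2.60, SE 0.30) and Kdr (-2.09, SE 0.26). Vegfa fell by 2.69 (SE 0.39, adjusted p = 1.1e-07). Hair follicle genes rose in 13 of 23 (20 adjusted over the list alone; adjusted p = 0.66 with an estimated correlation), as Tchhl1 (3.10, SE 0.88), but this rested on untreated day 20 arrays 51 and 52, whose hair list levels were 7.98 and 7.77 beside a group SD of 2.38. Without these 2 arrays 1 hair gene rose, the list difference went from 1.89 to 0.65, and Tchhl1 differed by 1.53 (SE 0.82, adjusted p = 0.23). Pan-endothelial genes fell in 25 of 28 without them as well. In all 3776 genes changed, 1758 higher and 2018 lower; the count was 1929 without the 2 arrays, 2450 with adjacent arrays averaged and 2988 with the RNA ratios as covariates.

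The calls against control overlapped between days. Days 5 and 20 shared 2593 higher and 2310 lower genes, where independent lists of these sizes would share 932 and 675. Fold changes correlated at 0.84 across genes, with a covariance of 0.502 against 0.028 for simulated unchanged groups and 0.479 with the control arrays split; the split parts shared 1923 and 1811 genes. Days 5 and 60 shared 1528 and 1909 (769 and 618 for independent lists, covariance 0.344, simulated 0.029, split 0.328), and days 20 and 60 shared 1365 and 1763 (626 and 458, covariance 0.268, simulated 0.027, split 0.240). Genes are not independent replicates, and part of each overlap may come from the shared control arrays. The split may not remove this, since adjacent control arrays resembled each other and fell in different parts.

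**Figure D2:**
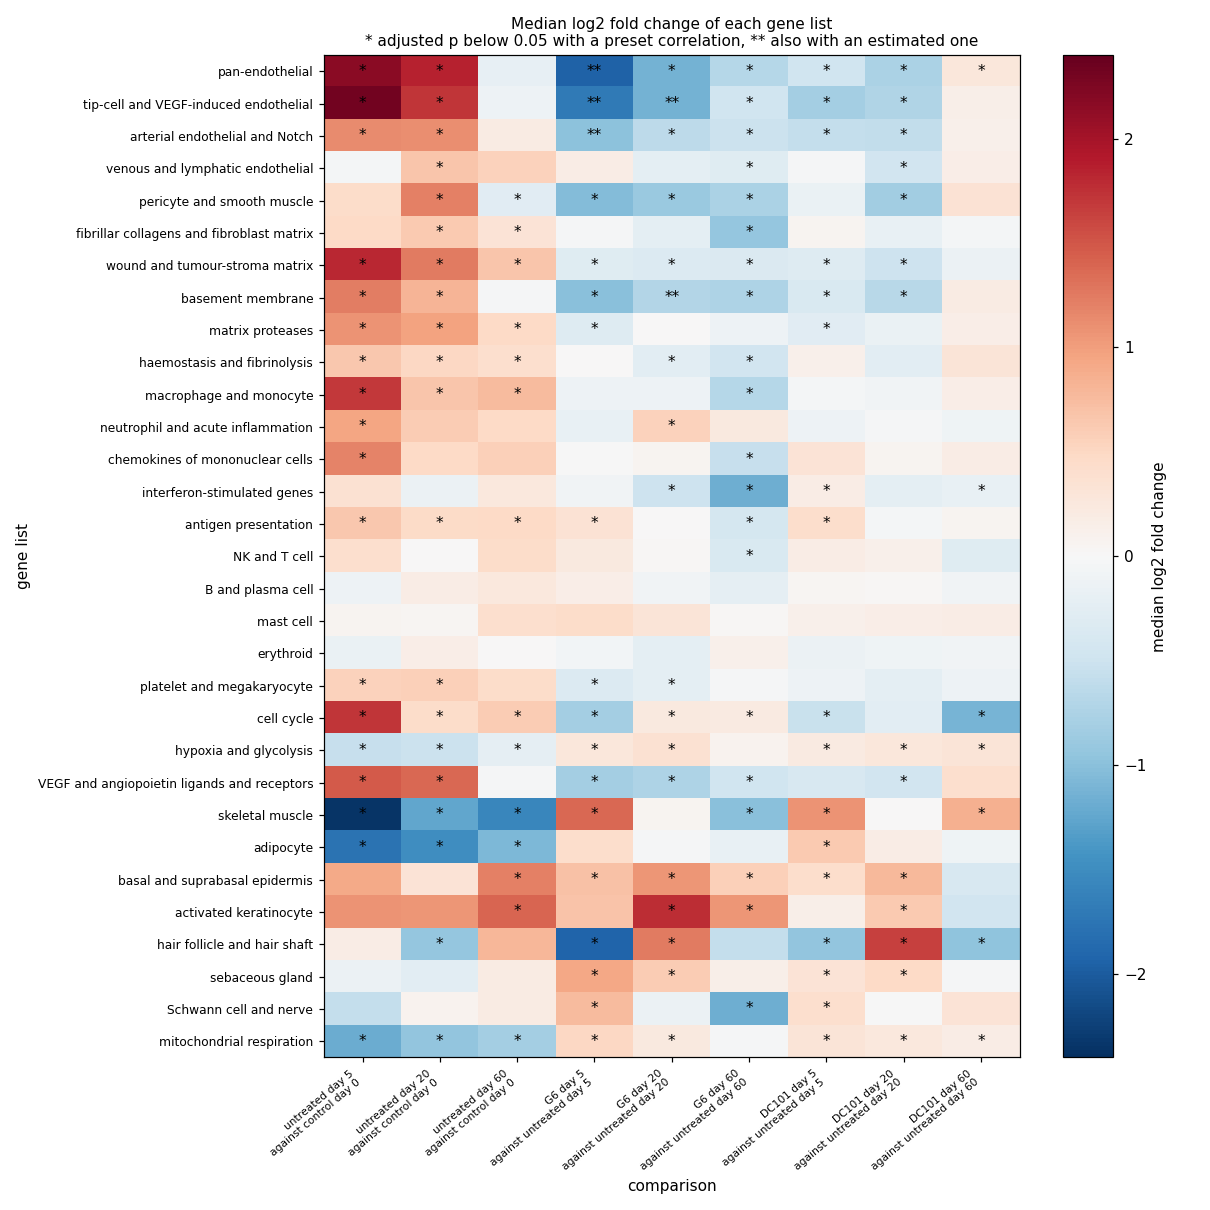
Median log2 fold change of each of the 31 gene lists (rows) in the 9 main comparisons (columns); colour gives the median and stars mark lists past the adjusted threshold. The pan-endothelial median goes from 2.17 in untreated tissue against control at day 5 to -1.95 with G6 against untreated tissue, and the B and plasma cell, mast cell and erythroid lists carry no star.

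Each antibody was then set against untreated, virus-injected tissue of the same day. With G6 at day 5 endothelial genes were lower than in untreated tissue, toward the control level. The pan-endothelial list level was 10.94 ± 0.41 with G6 and 10.71 ± 0.23 in control tissue, and the tip-cell one 11.14 ± 0.32 and 10.52 ± 0.15 (n = 8 each). G6 arrays 13 and 14 stood above the other 6 (Esm1 11.49 and 11.16, Actb 3' to 5' ratios 2.35 and 2.43); without them Esm1 was 8.81 ± 0.31 (n = 6) and the tip-cell level 10.97 ± 0.06 (n = 6). Esm1 fell by 4.71 (SE 0.56, adjusted p = 5.2e-10, 8 of 8 arrays), to 9.44 ± 1.20 (n = 8) against 8.18 ± 0.78 (n = 8) in control tissue. Flt1 fell by 2.60 (SE 0.30, adjusted p = 3.1e-10) to 10.65 ± 0.57 (control 10.10 ± 0.51), and Kdr fell by 2.21 (SE 0.26, adjusted p = 7.1e-10) to 11.06 ± 0.70 (control 10.78 ± 0.33). Of 28 pan-endothelial genes 25 fell and 1 rose (25 and 1 adjusted over the list alone), including Icam2 (-3.15, SE 0.37) and Emcn (-3.11, SE 0.33). Tip-cell genes fell in 18 of 24 (18), arterial genes in 14 of 19 (15), as Notch4 (-3.73, SE 0.37), and basement membrane genes in 12 of 16 (12), as Nid2 (-2.93, SE 0.27). Another Notch4 probe set differed by 0.22 (adjusted p = 0.66). The pan-endothelial, tip-cell and arterial lists also passed with an estimated correlation (adjusted p = 0.048, 0.022 and 0.022), and basement membrane genes did not (adjusted p = 0.10 with an estimated correlation). Pericyte genes fell in 10 of 22 and rose in 4 (11 and 4 adjusted over the list alone; adjusted p = 0.42 with an estimated correlation).

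Other tissue genes moved with G6 at day 5. Cell cycle genes fell in 20 of 30 (26 adjusted over the list alone), and hair follicle genes in 12 of 23 (19; 5 without arrays 13 and 14), as Krt33a (-3.66, SE 0.99). Skeletal muscle genes rose in 19 of 24 (23), as Casq1 (2.25, SE 0.55), respiratory genes in 19 of 27 (21), and Schwann cell genes in 7 of 13 (7), as S100b (2.04, SE 0.32). With an estimated correlation their adjusted p was 0.42, 0.42, 0.42, 0.42 and 0.32. The skeletal muscle list level was 15.03 ± 0.48 with G6, 13.68 ± 0.26 untreated and 15.86 ± 0.41 in control tissue (n = 8 each). Macrophage genes were not among the 18 lists that passed. The glucocorticoid-inducible gene Klf15 was at least 2.06-fold and the epidermal lipoxygenase Alox12b at least 1.92-fold higher. Limma called 4667 genes, 2463 higher and 2204 lower, 1313 of them at least 2-fold. The median Actb 3' to 5' ratio was 1.76 with G6 and 1.62 untreated, and the Gapdh ratio 1.24 and 1.03; 5072 genes passed with both as covariates.

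With G6 at day 20 the endothelial genes were again lower. Pan-endothelial genes fell in 22 of 28 (27 adjusted over the list alone), as Gpihbp1 (-1.86, SE 0.30) and Icam2 (-1.72, SE 0.37). Tip-cell genes fell in 18 of 24 (19), as Kcne3 (-2.04, SE 0.41) and the apelin receptor Aplnr (-1.93, SE 0.29), and basement membrane genes in 9 of 16 (14). Tip-cell and basement membrane lists also passed with an estimated correlation (adjusted p = 0.027 and 0.043), and the pan-endothelial list did not (adjusted p = 0.053 with an estimated correlation). Flt1 fell by 1.55 (SE 0.30, adjusted p = 0.00043) and Kdr fell by 1.43 (SE 0.26, adjusted p = 0.00022), both in 8 of 8 arrays. Untreated arrays 51 and 52, with the highest pan-endothelial levels of their group (13.28 and 13.42), carried much of this. Without them 6 pan-endothelial, 4 tip-cell and 1 basement membrane genes fell, the pan-endothelial difference went from -1.11 to -0.82, and Flt1 differed by -1.10 (SE 0.30, adjusted p = 0.054) and Kdr by -0.97 (SE 0.25, adjusted p = 0.040). Alas2, the erythroid enzyme of haem synthesis, fell by 3.56 (SE 0.61).

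Some epidermal and inflammation genes rose with G6 at day 20. Activated keratinocyte genes rose in 11 of 20 (16 adjusted over the list alone; adjusted p = 0.059 with an estimated correlation), with Defb3 up by 4.00 (SE 1.20, adjusted p = 0.023), Krt6b by 2.55 (SE 0.74) and Sprr2f by 2.87 (SE 0.86). The neutrophil and acute inflammation list rose in 6 of 24 (8; adjusted p = 0.31 with an estimated correlation), through Saa3 (2.47, SE 0.46) and S100a9 (2.38, SE 0.77). Interferon-stimulated genes fell in 4 of 31 (6; adjusted p = 0.31 with an estimated correlation), as Rsad2 (-1.54, SE 0.29). In all 1469 genes changed, 584 higher and 885 lower, 449 at least 2-fold. The count was 98 without untreated arrays 51 and 52, when no activated keratinocyte gene passed (Defb3 4.36, adjusted p = 0.088). It was 841 with adjacent arrays as a random block, 516 with them averaged, 2827 with array weights, 1022 with the RNA ratios as covariates and 89 with only these 2 groups in the fit.

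With G6 at day 60 interferon, matrix and nerve genes were lower. Interferon-stimulated genes fell in 24 of 31 (29 adjusted over the list alone), as Oasl2 (-2.04, SE 0.35), Rsad2 (-2.00, SE 0.29, adjusted p = 6.8e-06) and Ifi44l (-2.39, SE 0.42). Fibroblast matrix genes fell in 13 of 21 (18), as Loxl1 (-1.55, SE 0.25), and Schwann cell genes in 9 of 13 (11), as Mbp (-2.15, SE 0.43). Without G6 arrays 86 and 87, which stood apart, Mbp differed by -1.26 (SE 0.37). Another Mbp probe set differed by 0.09 (adjusted p = 0.9). Macrophage genes fell in 13 of 26 (18), as Aif1 (-1.17, SE 0.31), and pan-endothelial genes in 11 of 28 (16), as Vwf (-1.61, SE 0.30). Untreated array 77 had the highest pan-endothelial level of its group (11.72, others 9.94 to 10.7), and no fit left it out. Flt1 differed by -0.75 (SE 0.30, adjusted p = 0.087) and Kdr by -0.16 (SE 0.26, adjusted p = 0.75). Of the 20 lists that passed, 17 were lower, and none passed with an estimated correlation (adjusted p = 0.12 for interferon, matrix and Schwann cell genes, 0.28 for macrophage and pan-endothelial genes, each with an estimated correlation). Of 1751 genes called, 388 were higher and 1363 lower, 335 at least 2-fold. The median Actb 3' to 5' ratio was 2.22 with G6 and 1.88 untreated, while the Gapdh ratio was 0.846 and 0.95. With both ratios as covariates 27 genes remained. The count was 1146 without arrays 86 and 87, 1121 with adjacent arrays as a random block, 766 with them averaged and 344 with only these 2 groups in the fit.

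**Figure D3:**
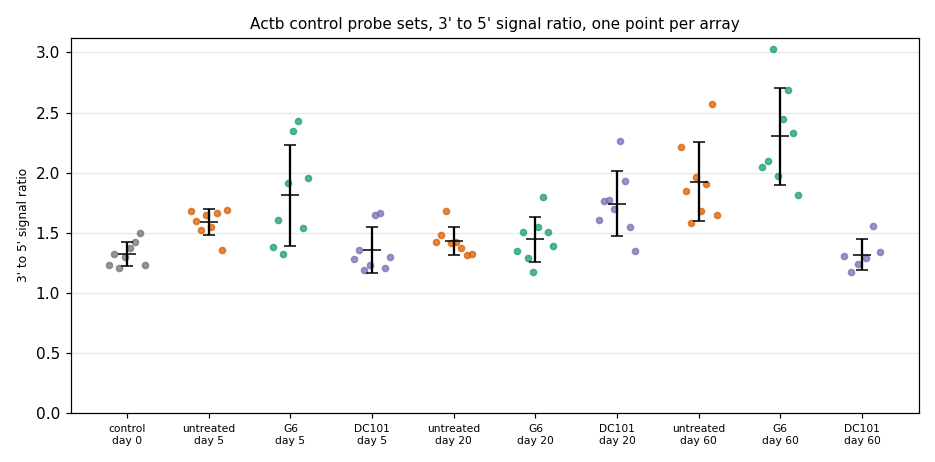
Ratio of 3' to 5' signal of the Actb control probe sets by group; points are arrays and bars are the mean with SD. At day 60 the G6 arrays run from 1.81 to 3.03 and the DC101 arrays from 1.17 to 1.56.

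With DC101 at day 5 the endothelial genes were lowered in part. Flt1 fell by 1.22 (SE 0.30, adjusted p = 0.0039, 8 of 8 arrays) and Kdr differed by -0.66 (SE 0.26, adjusted p = 0.089). Tip-cell genes fell in 10 of 24 (15 adjusted over the list alone), as the chemokine receptor Cxcr4 (-1.58, SE 0.29) and placental growth factor Pgf (-1.60, SE 0.44). Arterial genes fell in 4 of 19 (6), as Dll4 (-1.21, SE 0.21) and Sox17 (-1.17, SE 0.28), and pan-endothelial genes in 6 of 28 (9), as Sox18 (-1.23, SE 0.28). The microglial and monocyte receptor Cx3cr1 fell by 1.92 (SE 0.22, adjusted p = 8.1e-10) and Ch25h fell by 1.89 (SE 0.23). Klf15 was at least 2.70-fold higher, and the fat genes Adipoq (1.49, SE 0.46) and Slc2a4 (1.09, SE 0.36) rose, with 4 of 18 adipocyte genes risen (7). Skeletal muscle genes rose in 3 of 24 (13). Limma called 1732 genes, 686 higher and 1046 lower, 295 at least 2-fold. Of 31 lists 17 passed and none with an estimated correlation (adjusted p = 0.58 for tip-cell, arterial, adipocyte and muscle genes and 0.60 for pan-endothelial genes, each with an estimated correlation). The count was 1105 with adjacent arrays as a random block, 823 with them averaged, 4577 with array weights and 3288 with only these 2 groups in the fit. The median Actb ratio was 1.29 with DC101 and 1.62 untreated, and the Gapdh ratio 0.847 and 1.03. With both as covariates 1203 genes passed, 1030 of them among the 1732, with 7 tip-cell and 6 pan-endothelial genes lower.

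With DC101 at day 20 endothelial and mural genes were lower, in part through 2 untreated arrays. Pan-endothelial genes fell in 15 of 28 (23 adjusted over the list alone), as Cdh5 (-1.43, SE 0.29) and Cd93 (-1.37, SE 0.31). Tip-cell genes fell in 12 of 24 (14), as Kcne3 (-2.14, SE 0.41), pericyte genes in 9 of 22 (17), as Actg2 (-1.81, SE 0.42), and basement membrane genes in 10 of 16 (12), as Nid2 (-1.67, SE 0.27) and Col18a1 (-1.40, SE 0.24). Their adjusted p was 0.17, 0.095, 0.12 and 0.095 with an estimated correlation. Flt1 differed by -0.70 (SE 0.30, adjusted p = 0.14) and Kdr by -0.51 (SE 0.26, adjusted p = 0.24). Without untreated arrays 51 and 52, 1 pan-endothelial, 5 tip-cell, 1 pericyte and 4 basement membrane genes fell. The pan-endothelial difference went from -0.82 to -0.53, and Flt1 then differed by -0.26 (SE 0.30) and Kdr by -0.05 (SE 0.25). Keratins Krt17 (1.41, SE 0.46) and Krt6a (1.39, SE 0.45) rose, as did the hair gene Tchh (2.41, SE 0.69); adjusted p was 0.53 for keratinocyte and 0.41 for hair genes with an estimated correlation. These rises also rested on arrays 51 and 52: without them Tchh differed by 0.52 (SE 0.46, adjusted p = 0.70), Krt17 by 0.65 (adjusted p = 0.54) and Krt6a by 0.88 (adjusted p = 0.40), and the hair list difference went from 1.56 to 0.32. In all 1132 genes changed, 359 higher and 773 lower, 158 at least 2-fold. The count was 151 without arrays 51 and 52, 614 with adjacent arrays as a random block, 295 with them averaged and 76 with only these 2 groups in the fit. The median Actb ratio was 1.74 with DC101 and 1.42 untreated. With both ratios as covariates 823 genes passed, 590 of them among the 1132, with 9 pan-endothelial, 11 tip-cell and 3 pericyte genes lower.

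With DC101 at day 60 proliferation genes were lower. Cell cycle genes fell in 21 of 30 (27 adjusted over the list alone; adjusted p = 0.80 with an estimated correlation), with Mki67 at 10.60 ± 0.91 (n = 6) against 12.56 ± 0.40 (n = 8), a change of -1.96 in log2 (SE 0.38, adjusted p = 4e-04). The DC101 arrays were not alike in this: Mki67 was 9.67 to 10.48 in arrays 89 to 92 but 11.84 and 11.59 in arrays 93 and 94. The cell cycle list level was 8.97 to 9.73 in arrays 89 to 92, and 10.25 and 10.03 in arrays 93 and 94 (untreated mean 10.54). No fit left arrays 93 and 94 out. The chemokine Cxcl9 was at least 2.46-fold lower and Rsad2 fell by 1.34 (SE 0.31). The stress-induced genes Depp1 (2.53, SE 0.27, adjusted p = 1.3e-10) and Cirbp (1.72, SE 0.15, adjusted p = 5e-13) rose in 6 of 6 arrays. Skeletal muscle genes rose in 2 of 24 (2; adjusted p = 0.80 with an estimated correlation), as Ryr1 (1.83, SE 0.58), and the list level was 15.27 ± 0.33 (n = 6) against 14.38 ± 1.27 (n = 8). Without untreated array 79 (11.34) the untreated level was 14.82 ± 0.35 (n = 7), the difference went from 0.88 to 0.45, and Ryr1 differed by 1.40 (SE 0.56, adjusted p = 0.11). Flt1 differed by 0.15 (SE 0.33, adjusted p = 0.80) and Kdr by 0.49 (SE 0.29, adjusted p = 0.26). Of 1701 genes, 684 were higher and 1017 lower, 230 at least 2-fold. Of the lists 7 passed, and none with an estimated correlation. The Actb ratios ran from 1.17 to 1.56 with DC101 and from 1.58 to 2.57 untreated, and with both ratios as covariates 183 genes passed, 161 of them among the 1701; the count was 995 with adjacent arrays as a random block, 697 with them averaged and 4541 with array weights.

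The antibodies were compared with each other at each day, at their different doses. At day 5 vessel genes were lower with G6 than with DC101. Pan-endothelial genes were lower in 22 of 28 (24 adjusted over the list alone), tip-cell genes in 15 of 24 (18) and arterial genes in 8 of 19 (8), and all 3 lists passed with an estimated correlation (adjusted p = 0.038 each). Esm1 differed by -3.91 (SE 0.56, adjusted p = 4.8e-07), Fam167b by -3.63 (SE 0.50), Ushbp1 by -3.53 (SE 0.41), Flt1 by -1.38 (SE 0.30, adjusted p = 0.00086) and Kdr by -1.55 (SE 0.26, adjusted p = 1.8e-05), each in 8 of 8 G6 arrays against the DC101 mean. Pecam1 stood at 10.30 ± 0.58 with G6 and 11.80 ± 0.68 with DC101, beside 10.29 ± 0.46 in control tissue (n = 8 each). Vegfa differed by -0.03 (SE 0.39, adjusted p = 0.98). The progesterone receptor gene Pgr was higher with G6 by 2.01 (SE 0.44). In all 1688 genes differed, 856 higher and 832 lower with G6; with the mean of all probe sets 38.3% of 1581 calls were higher, against 50.7% here. The count was 1117 with adjacent arrays as a random block, 901 with them averaged, 2586 with array weights and 1773 with the RNA ratios as covariates, 1026 of these shared with the 1688.

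At day 20 the antibodies differed in 36 genes, 20 higher and 16 lower with G6. Aplnr (-1.39, SE 0.29, adjusted p = 0.020), Btnl9 (-1.44, SE 0.35) and Alas2 (-2.50, SE 0.61) were lower with G6, and Ajuba (1.01, SE 0.23) and Bcl3 (0.90, SE 0.19) higher. Flt1 differed by -0.85 (SE 0.30, adjusted p = 0.18) and Kdr by -0.92 (SE 0.26, adjusted p = 0.092). Of 100 splits of the arrays 7 gave as many genes, and the count was 0 in limma with adjacent arrays as a random block or averaged, 593 with array weights and 91 with the RNA ratios as covariates; 1882 genes had an unadjusted p under 0.05.

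At day 60 the antibodies differed in 5955 genes, 2732 higher and 3223 lower with G6. Cell cycle genes were higher with G6 in 27 of 30 (27 adjusted over the list alone) and activated keratinocyte genes in 10 of 20 (11), and Rptn differed by 3.20 (SE 0.66). Skeletal muscle genes were lower in 24 of 24 (24), as Actn3 (-3.08, SE 0.80), as were pan-endothelial genes in 21 of 28 (24) and Schwann cell genes in 12 of 13 (12). Their adjusted p was 0.39, 0.42, 0.42, 0.39 and 0.39 with an estimated correlation. DC101 arrays 93 and 94 had cell cycle levels of 10.25 and 10.03, above the 8.97 to 9.73 of DC101 arrays 89 to 92. G6 arrays 86 and 87 had muscle list levels of 10.32 and 10.60; without them 7 of 24 muscle genes were lower, the list difference went from -1.89 to -0.91, and Actn3 differed by -1.19 (SE 0.58, adjusted p = 0.099). Keratinocyte genes were then higher in 6 of 20, and 5389 genes differed in all. Flt1 differed by -0.91 (SE 0.33, adjusted p = 0.021) and Kdr by -0.65 (SE 0.29, adjusted p = 0.062). The Actb 3' to 5' ratios of these groups did not overlap, and with both ratios as covariates limma called 0 genes. Actn3 then differed by 0.5 (adjusted p = 0.9), and the skeletal muscle median changed sign. Without the ratios 7001 genes had an unadjusted p under 0.05.

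The antibodies shared calls at days 5 and 20, while at day 60 more calls were opposite than shared. At day 5, 525 genes were higher and 611 lower with both antibodies, where independent lists would share 115 and 157. The covariance of fold changes was 0.200, against 0.028 for simulated unchanged groups and 0.191 with the untreated arrays split, which shared 158 and 232 genes. At day 20, 84 were higher and 424 lower with both (14 and 46 for independent lists; covariance 0.114, simulated 0.027, split 0.108), and the split parts shared 1 and 72. Without untreated arrays 51 and 52, 0 were higher and 16 lower with both (0.04 and 0.56 for independent lists, covariance 0.056), though fewer arrays also give fewer calls. At day 60, 34 were higher and 43 lower with both (18 and 94), 119 moved in opposite directions, and the covariance was -0.036 (simulated 0.027, split -0.043). The Actb ratios of the antibody groups at day 60 lay on opposite sides of untreated tissue (median 2.22 with G6 and 1.88 untreated, 1.17 to 1.56 with DC101). The Gapdh medians did not: 0.846 with G6 and 0.815 with DC101 were both below 0.95 in untreated tissue. Of the calls, 71.3% with G6 and 80.1% with DC101 changed in the direction that the Actb difference predicts. With both ratios as covariates 27 and 183 genes passed. RNA integrity is therefore not excluded as a source of the opposite calls, though the Actb and Gapdh ratios disagree for G6. Part of the overlap may come from the shared untreated arrays. The split may not remove this at days 5 and 20, where adjacent untreated arrays resembled each other and fell in different parts.

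Tests of the antibody effect between days found 1349 genes whose G6 effect differed between days 5 and 20 (599 higher and 750 lower at day 20), and 11 between days 20 and 60. The first count was 655 with adjacent arrays as a random block, 430 with them averaged, 3397 with array weights and 2299 with only these groups in the fit, and the second 4, 0, 205 and 0. Esm1 was lowered less by G6 at day 20 than at day 5, by 2.91 (SE 0.79, adjusted p = 0.013), as was Pecam1, by 1.40 (SE 0.44, adjusted p = 0.034). For DC101, 267 genes differed between days 5 and 20 and 2678 between days 20 and 60; with both RNA ratios as covariates these counts were 116 and 631. The first was 126 with adjacent arrays as a random block, 57 with them averaged and 2017 with array weights, and the last 1219 with them averaged and 4964 with array weights. It was 1493 without untreated arrays 51 and 52, and that of G6 between days 20 and 60 was 0. Pan-endothelial genes were relatively higher at day 60 than at day 20 with DC101 in 15 of 28 (18 adjusted over the list alone, and adjusted p = 0.52 with an estimated correlation). The untreated pan-endothelial level was 12.46 at day 20 and 10.57 at day 60 (control 10.71), which left no rise to lower at day 60.

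The Ad-VEGF score summarised how far each array stood from control tissue along the genes that differed between untreated and control tissue at both other days. At day 5 it was -3.74 ± 0.66 in control, 0.23 ± 0.29 in untreated, -0.34 ± 0.63 in G6 and -0.22 ± 0.41 in DC101 arrays (n = 8 each). G6 differed from untreated tissue by -0.56 (exact permutation p = 0.0384, adjusted 0.115) and DC101 by -0.44 (exact permutation p = 0.0269, adjusted 0.115). At day 60 DC101 lay at -1.21 ± 0.38 (n = 6) and untreated tissue at -0.67 ± 0.43 (n = 8), a difference of -0.54 (exact permutation p = 0.0163, adjusted 0.115). Untreated array 79 widened the day 60 difference, with a score of 0.24 (others -1.08 to -0.51), and no comparison of scores left it out. The other 6 differences had adjusted values from 0.333 to 0.982. No difference passed the adjustment over 9 comparisons. The score's lower genes numbered 461 at day 5 and its higher genes 187; the milk protein gene Csn1s2a and the muscle gene Xirp1 met the rule for the lower ones.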

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

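Tests of the mammary gland, fading vector effect and antibody explanations, of RNA integrity and muscle at day 5, and every fit with RNA ratios as covariates or without arrays that stood apart were chosen only after the result was seen; the bounds for the slopes and muscle at day 60 and for the splits of the arrays were written before their values were seen.

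Single arrays stood far from the rest of their group in 9 of 192 groups of values tested, where chance picks out about 1 in 20. In control tissue 1 array had Kdr at 10.06, against 10.69 to 11.11 in the others, and with DC101 at day 20 array 72 had Col1a1 at 13.03, against 13.97 to 14.7. In untreated tissue at day 60 array 77 stood high for Angpt2 (11.04), Rgs5 (15.55), Acta2 (16.6) and the pan-endothelial list (11.72, others 9.94 to 10.7). In the same group array 79 had the skeletal muscle list at 11.34 (others 14.45 to 15.52) and an Ad-VEGF score of 0.24 (others -1.08 to -0.51), and array 75 had the hair list at 11.17 (others 13.15 to 14.58).

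Antibody effects differed between days by interaction tests. The G6 effect differed between days 5 and 20 in 1349 genes, including Pecam1 (1.40) and Esm1 (2.91), lowered less at day 20, and Mki67 (1.47, adjusted p = 0.049), which changed by -1.20 with G6 at day 5 and by 0.28 (adjusted p = 0.70) at day 20; without untreated arrays 51 and 52 it had 1.16 (adjusted p = 0.15). Between days 20 and 60 the G6 effect differed in 11 genes. The DC101 effect differed between days 5 and 20 in 267 genes and between days 20 and 60 in 2678, including Apln (1.22, adjusted p = 0.0021), Angpt2 (1.27), Plvap (1.58) and Mki67 (-1.73). Without untreated arrays 51 and 52 these were Apln 0.90 (adjusted p = 0.022), Angpt2 0.74 (adjusted p = 0.19), Plvap 1.32 (adjusted p = 0.025) and Mki67 -1.41 (adjusted p = 0.072). In untreated tissue at days 20 and 60 Apln stood at 11.55 and 10.05 (control 10.2) and Angpt2 at 11.67 and 9.83 (control 9.43). Plvap stood at 14.28 and 11.98 (control 12.54). Little or no rise over control was thus left in Apln, Angpt2 and Plvap at day 60 for DC101 to lower. With DC101 at day 60 Apln (10.07) and Angpt2 (9.78) were near untreated tissue. Plvap was not: with DC101 it was below untreated tissue at day 20 (13.59 ± 0.59, n = 8). At day 60 it was above untreated tissue (12.87 ± 0.65, n = 6, untreated SD 0.99), so its interaction also holds a higher level with DC101. Outside the genes analysed, 1582, 1693 and 1063 probe sets without a single gene symbol were higher in untreated than in control tissue at days 5, 20 and 60, of 5818 that passed the filter.

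Other splits of the same arrays into groups of the same sizes, 100 drawn for each comparison with the real one included, show where chance can be excluded if arrays are independent samples. Adjacent arrays may share an animal, which the splits do not model. For untreated against control tissue only the real split gave as many genes: 7767 against at most 5532 at day 5, 6056 against 4040 at day 20 and 5241 against 3948 at day 60 (1 of 100 each). The same held for day 20 against day 5 (2973, highest other 902), day 60 against day 20 (3776, 2549), G6 at day 5 (4667, 2697), DC101 at day 5 (1732, 604), day 20 (1132, 184) and day 60 (1701, 292), and G6 against DC101 at day 5 (1688, 548) and day 60 (5955, 3916). With G6 at day 20, 2 of 100 splits gave as many genes (1469, highest other 1534), as at day 60 (1751, 2103), a share under 0.05 that holds only on that assumption; with adjacent arrays averaged 516 and 766 genes were called, and without untreated arrays 51 and 52 G6 at day 20 gave 98. For G6 against DC101 at day 20 it cannot: 7 of 100 splits gave as many as 36 genes, and the highest other gave 1008. Of the interactions, 1 of 100 splits gave as many for G6 between days 5 and 20 (1349, 258) and DC101 between days 20 and 60 (2678, 1245). The number was 2 for DC101 between days 5 and 20 (267, 464) and 6 for G6 between days 20 and 60 (11, 1722). These splits mixed antibody and untreated arrays within each day, so real antibody effects at either day can enter the contrast. They are no test of equal effects and do not decide whether chance gave the interaction counts. Why some splits called several times the real count was not tested.

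Most genes of milk and mammary epithelium were high in control arrays and low at every later day. Of 16 measured mammary genes 13 fell at day 60, with medians of -3.91, -3.70 and -3.00 at days 5, 20 and 60, and Krt18 stood at 12.86 in control tissue and 9.30 at day 60; Epcam (12.96 and 13.08), Spint1 (11.86 and 12.38) and Elf5 did not fall. Mammary gland in the control samples may explain this, since the set stayed low while the brighter Vegfa probe set was near its control level at day 60. An effect of the vector that fades with Vegfa cannot be told apart, because the day 60 median was 76.8% of the day 5 one and no empty vector group exists.

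Many more genes differed between G6 and DC101 at day 60 than at day 20. Across genes, the slope on the Actb 3' to 5' ratio within groups correlated at 0.57 with the difference, so a difference in RNA integrity may account for part of it; genes are not independent replicates. With both ratios as covariates the skeletal muscle median went from -1.83 to 0.45, the cell cycle median from 1.36 to 0.83 and the pan-endothelial one from -0.99 to -0.64. Muscle content as a covariate left 3887 genes and does not decide. A difference between the antibodies themselves cannot be told apart, since 0 G6 arrays lay within the range of the DC101 Actb ratios. The Gapdh ratios of these groups overlapped (0.805 to 1.176 with G6, 0.783 to 0.819 with DC101).

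Endothelial genes were lower with G6 than with DC101 at day 5. RNA integrity as the whole cause is argued against by a pan-endothelial median of -1.26 with both ratios as covariates (-1.39 without), with 19 of 28 genes lower past the threshold. More muscle and less of every other tissue is argued against by the macrophage median of -0.17 and the fibroblast matrix median of -0.03. A stronger endothelial effect of G6 at these doses may be the explanation, as a hypothesis. Dose, time of sampling and shared animals stay untested.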

How the results depend on the processing

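The alternatives with RNA ratios as covariates, adjacent arrays as a block or averaged, a pseudocount of 256, 75 arrays, and without arrays that stood apart were chosen after seeing the data. Of the gene counts under all alternatives 175 stayed within 1.5 times and 80 moved; 5156 values of named genes kept direction and side of the threshold, 642 lost the threshold, 15 gained it and 47 reversed. Except as said, the cause was not tested. Asking for at least 2-fold gives fewer genes by construction: for untreated tissue against control 2558, 1545 and 1113, for day 20 against day 5 648, for day 60 against day 20 857, for G6 1313, 449 and 335, for DC101 295, 158 and 230, for G6 against DC101 250, 10 and 1650, and for the interactions 551, 3, 81 and 818. Without a filter the G6 interaction between days 20 and 60 gave 6 genes, and 20 with a pseudocount of 256. With the mean of probe sets G6 against DC101 at day 20 gave 15 genes, and at day 5 38.3% of calls were higher with G6, against 50.7%. Array weights gave 5233 genes for day 20 against day 5, 2827 for G6 at day 20, 4577 and 4541 for DC101 at days 5 and 60, 2586 and 593 for G6 against DC101 at days 5 and 20, and 3397, 205, 2017 and 4964 for the interactions. RNA ratios as covariates gave 2360 genes for untreated tissue at day 60 against control, 27 for G6 (7.4% higher, against 22.2%) and 183 for DC101 at day 60, 91 and 0 for G6 against DC101 at days 20 and 60, and 5, 116 and 631 for the G6 interaction between days 20 and 60 and the DC101 interactions. Adjacent arrays as a random block (consensus correlation 0.18) gave 841 and 1121 genes for G6 at days 20 and 60, 1105, 614 and 995 for DC101, 1117 and 0 for G6 against DC101 at days 5 and 20, and 655, 4 and 126 for the first 3 interactions. Averaging them, which leaves fewer samples, gave 1937 genes for day 20 against day 5, 2450 for day 60 against day 20, 516 and 766 for G6 at days 20 and 60, 823, 295 and 697 for DC101, 901 and 0 for G6 against DC101 at days 5 and 20, and 430, 0, 57 and 1219 for the interactions. With 75 arrays G6 against DC101 at day 20 gave 96 genes, the G6 interaction between days 20 and 60 gave 52 and the DC101 one between days 5 and 20 gave 481. Without untreated arrays 51 and 52, day 60 against day 20 gave 1929 genes, G6 and DC101 at day 20 98 and 151, and the interactions between days 20 and 60 0 for G6 and 1493 for DC101, and Vegfa became 0.1 for G6 and 0.02 for DC101 at day 20. Without G6 arrays 86 and 87, G6 at day 60 gave 1146 genes, its interaction with day 20 44, and Vegfa -0.36; without untreated array 79 that interaction gave 22. With only the groups compared in the fit, G6 gave 89 and 344 genes at days 20 and 60, DC101 3288 and 76 at days 5 and 20, G6 against DC101 0 at day 20, and the G6 interactions 2299 and 0. The Ad-VEGF score of G6 against untreated tissue at day 60, near 0, changed sign to -0.016 with a pseudocount of 64, -0.002 without a filter, -0.021 with quantile normalization, -0.0042 with a pseudocount of 256 and -0.37 with 75 arrays. That of DC101 at day 20 became 0.11 with a pseudocount of 256 and 0.32 with 75 arrays, and that of G6 against DC101 at day 20 became -0.0082 with 75 arrays. Vegfa with the mean of probe sets became 0.38 and 0.03 for G6 at days 5 and 20 and 0.43 for G6 against DC101 at day 5. With array weights it became -0.15 for G6 at day 60 and -0.12 for G6 against DC101 at day 20. With RNA ratios as covariates it became 0.22 for untreated tissue at day 60, 0.27 and -0.05 for G6 against DC101 at days 5 and 20, and with 75 arrays -0.36 for G6 at day 60. In its other probe set Vegfa was -2.03 and -1.51 against control at days 5 and 20, 0.52 and 0.31 between days, 1.16 and 0.59 with G6 at days 5 and 20, 0.28 and 0.32 with DC101 at days 5 and 20, and 0.88 for G6 against DC101 at day 5. RNA ratios as covariates turned Myoz3 and Actn3 to 0.5 each for G6 against DC101 at day 60. Other probe sets reversed Trem2 (-0.24), Thrsp (0.14) and Bub1b (-0.24) at day 5 against control, Col12a1 (-0.21 and -0.16) and Tyms (-0.25) at day 20, and Synpo2 (0.44 and 0.2), Col8a1 (-0.06) and Bub1b (-0.32) at day 60. With G6 they reversed Notch4 at days 5, 20 and 60 (0.22, 0.1 and 0.04, and 0.33 in a further probe set), and at day 60 Rptn (0), Nkx2-4 (-0.02), Mbp (0.09), Reln (0.64) and Flt1 (0.21). With DC101 they reversed Atp5c1 (-0.12) at day 5, Notch4 (0.25) and Higd1a (-0.01) at day 20, and Trim12c (0.13) and Tyms (0.69) at day 60. Signal near background limits dim probe sets, where the filter level of 331 and the pseudocount set the size of a fold.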

Other observations

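The tests in this part were all chosen only after the result was seen. Arrays of adjacent running numbers resembled each other within a group in some groups. In 5 of 10 groups (control, untreated, G6 and DC101 at day 5, and untreated at day 20) the adjacent pairing had the highest mean correlation of residuals of all 105 pairings. In G6, DC101 and untreated tissue at days 20, 20 and 60 it ranked 66, 77 and 82. With G6 at day 60 it ranked 17 of 105, and with DC101 at day 60 it ranked 2 of 15. Pairs of arrays from single animals would leave 4 animals in a group of 8 arrays, fewer than the 5 or more that the design describes. Some arrays may share an animal, but the labels do not tie arrays to animals and order of processing cannot be told apart.

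Clock and glucocorticoid genes rose with DC101 at day 60: Per1 by 1.55 (SE 0.15), Nr1d1 by 1.70 (SE 0.23) and Dbp by 1.23 (SE 0.22). The untreated group was itself low, with clock output genes fallen in 7 of 10 against control (Nr1d1 10.95 in control, 9.27 untreated and 10.97 with DC101). Per1 was an exception, at 10.46 in control, 10.32 untreated and 11.87 with DC101. Clock output genes also rose at day 5, in 8 of 10 with G6 and 6 of 10 with DC101, so the rise was not particular to DC101 at day 60. There too the untreated group was low, with 8 of 10 fallen and 1 risen against control. Of 12 measured glucocorticoid-responsive genes outside the clock set 8 rose and 0 fell. Fkbp5 (-0.04), Zbtb16 (0.33), Mt1 (-0.02) and Mt2 (-0.26) did not pass. A glucocorticoid response, to handling for example, may account for part of the rise. RNA integrity also differed: across genes the slope on the Actb ratio correlated at -0.48 with this comparison, 80.1% of called genes changed in the direction that the difference in ratio predicts, and 161 of 1701 calls passed with both ratios as covariates. Per1 (1.61, SE 0.18, adjusted p = 2.3e-09), Nr1d1 (1.32, SE 0.24, adjusted p = 0.00068) and Dbp (0.93, SE 0.24, adjusted p = 0.030) were among these, as were 5 of the 8 glucocorticoid genes. Tsc22d3, Klf15 and Dusp1 were not. Another time of day at harvest cannot be told apart, since the opposite-phase clock genes had a median change of -0.02 with 0 of 5 past the limma threshold, and the labels give no hour of harvest. At day 5 with DC101, 11 of 13 glucocorticoid genes rose, as Klf15 (at least 2.70-fold), Zbtb16 (1.93, SE 0.24) and Per1 (1.53, SE 0.14), and with G6 9 of 13 rose and 1 fell. For Klf15 and Zbtb16 this was a rise from a low untreated level toward control. Klf15 was 10.72 in control, 6.24 untreated and 9.87 with DC101, and Zbtb16 was 12.26, 9.83 and 11.75. Per1 rose above control (10.46, 10.84 and 12.37). Of the 13 genes 5 rose and 4 fell in untreated tissue at day 5 against control.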
